A study of Mus musculus with 11 samples.

How the data were processed

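The series measured where Xist RNA lies on the genome of mouse (Mus musculus) cells by RNA antisense purification followed by DNA sequencing (RAP-seq). Xist is the long noncoding RNA that coats and silences an X chromosome in female mammals. In RAP-seq, per the labels' protocols, cells were crosslinked, chromatin was fragmented by sonication and DNase, biotinylated oligonucleotide probes against Xist were captured on streptavidin beads, and the DNA that came along was eluted and sequenced. A part of each sample was set aside before capture as input. The labels list 11 samples. These are pulldowns from female epiblast-like cells (EpiLCs, embryonic stem cells moved toward the epiblast with Activin A and bFGF) at day 2 (D2, n = 2) and day 4 (D4, n = 2), from female mouse embryonic fibroblasts (MEFs, n = 1) and from male MEFs (n = 1), plus 5 inputs. Peak lists of the 6 pulldowns were analysed, with 1 list per library. The inputs were not analysed here as separate data.

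Per the submitters' processing notes, Trim Galore 0.4.1, Bowtie2 2.2.9, SAMtools 1.9, Picard, bedtools 2.26.0 and MACS2 2.2.7.1 were used with the genome build mm9. The notes used here give no settings, and which input each list was called against is not given in the sources used here. The 3 EpiLC inputs carry a replicate number but no day in the labels. D2 and D4 lists of 1 replicate number may therefore share an input or have separate ones. The deposited lists have no header and follow the broad-peak layout. Each row gives a start and an end in bp. The deposited score was found to equal the −log10 q multiplied by 10 and rounded down, and was not used further. The deposited fold enrichment is a linear ratio over the peak caller's background. The deposited −log10 p and −log10 q are the peak caller's values for that peak. These are the authors' own values for each peak and were used here to describe, rank or filter peaks within a list. Every list held peaks on chromosomes 1 to 19 only, so the X chromosome was not analysed here. The lowest −log10 q was between 1.30 and 1.34 in the 6 lists, and the shortest gap between neighbouring peaks of a list was 4001 bp. The lists carry no read counts, so the sequencing depth of each library is unknown and no counting interval can be given for a peak. The number of peaks a caller finds grows with depth. Coordinates are printed on mm9, counted from 1.

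The labels state that the replicate 1 EpiLC pulldowns of both days and the replicate 1 input re-analyse data deposited earlier, and do not state this for replicate 2. The replicate number was therefore taken to mark an earlier and a later data set and to pair the D2 and D4 libraries. As a check, the difference in covered share between replicates 1 and 2 at D2 correlated with that at D4 over 1175 bins of 1 Mb (r = 0.232, across bins, which are not independent replicates). Replicate 1 covered more than replicate 2 on both days (77.1 against 55.6 Mb at D2, 8.05 against 5.50 Mb at D4). The correlation can therefore arise without pairing and does not settle it. The labels do not say whether replicates came from separate cultures, so a spread between them may be technical.

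Peaks per library and the merged length under them were compared between D2 and D4 with a two-sided exact permutation test, which cannot give a p below 0.333 for 2 libraries against 2. Consensus regions of a day were the segments covered in both of its lists. Lists were compared by the share of regions of 1 list that overlapped the other by at least 1 bp. Each share was set against 1000 placements in which a list was shifted circularly along each chromosome, which keeps lengths and spacing. This permutation test is one-sided, and the smallest p it can give is 0.001. It tests positions in these libraries, not conditions. Because peaks lie in groups, shares were also set against local placements, with each peak moved by 100 to 500 kb. P-values were adjusted by Benjamini-Hochberg within families of 15 consensus overlaps and 30 ordered pairs of lists. The spread of peak density over chromosomes was tested against 100000 random draws in proportion to the extent between the first and last peak of any list. Distances between neighbouring peaks were tested against 1000 uniform placements. These last 2 tests and the local placements, which move each peak separately, treat peaks as independent. This overstates significance where peaks lie in groups.

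The regions named in the text follow a rule set before the data were examined, except the chromosome 6 window and the bins of 1 Mb, which were chosen after the values were seen. Under the rule they are the 5 D2 and the 5 D4 consensus regions with the best mean rank of fold enrichment and the 5 longest of each, and the 5 female MEF peaks without male overlap and the 5 male MEF peaks with the highest fold enrichment plus the 3 longest of each. The rule adds up to 10 segments called in all 6 lists and up to 10 called in all 5 female lists and not in the male list, and the 3 chromosomes with the highest and the 3 with the lowest density. A planned count of genes and gene groups under the regions was not run, because no mm9 gene annotation was used here, and no region was given a gene name. For the same reason, gene lists fixed beforehand for pluripotency, cell types, X inactivation, chromatin and gene families gave no count.

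The overlap test was tested on simulated lists with the peak numbers and lengths of 4 comparisons of real lists. With 5% of peaks planted on the other list it called 20 of 20 runs for D2 replicate 1 against D2 replicate 2 (8227 peaks), for D4 replicate 1 against D4 replicate 2 (1553 peaks), for female against male MEF (1020 peaks) and for male against female MEF (326 peaks). With none planted it called 0 of 20 runs in the first 3 comparisons and 1 of 20 in the last. These simulated lists were made by the same circular shift that the test uses. Few calls without planting thus follow by construction and do not show how the test behaves where real lists crowd in the same stretches. Counts of overlapping peaks equalled those of bedtools 2.31.1 in 30 of 30 ordered pairs. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives covered stricter peaks (−log10 q or fold enrichment of at least 3, the upper 50% by fold enrichment, lists cut to equal number), peaks joined within 10 kb, peaks of at least 2000 bp, other rules of overlap, other placements, the union of replicates, the replicate number as a block, and leaving out each replicate.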

Results

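The data were 6 lists of autosomal regions enriched in Xist pulldowns, from female EpiLCs at D2 and at D4 (n = 2 each), female MEFs (n = 1) and male MEFs (n = 1). The series asked where on the genome Xist RNA lies as female cells differentiate and in female and male fibroblasts. Male cells carry a single X chromosome and normally do not express Xist. The male list was therefore taken to show background of the pulldown in MEFs. The series held no male EpiLCs, so background there was not measured. The lowest −log10 p of the male list was 4.57, against 2.80 to 2.88 in the female lists, so weaker background could be missed. Sequencing depth is unknown for all 6 libraries. Values for MEFs come from 1 library each and have no replicate check.

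The female lists held long regions of modest enrichment, and the male list held short ones. Median peak length was 3930 and 3562 bp in D2 replicates 1 and 2, 2881 and 2764 bp in D4 replicates 1 and 2, 5518 bp in female MEFs and 1015 bp in male MEFs. Peaks of at least 100 kb numbered 75 and 42 at D2, 5 and 3 at D4, 21 in female MEFs and 0 in male MEFs. The authors' fold enrichment had medians between 2.61 and 2.91 in the 6 lists and showed little relation to peak length, with Spearman correlations across peaks of at most 0.0681. Its highest value was 14.1 and 11.8 in the D2 lists, 12.3 and 9.31 in the D4 lists, 6.43 in female MEFs and 15.1 in male MEFs.

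Far more autosomal regions were called at D2 than at D4. The D2 libraries held 8227 and 7544 peaks, a mean of 7886 ± 483 (SD, n = 2), and the D4 libraries held 1553 and 1148, a mean of 1351 ± 286 (SD, n = 2). The D2 mean was 5.84 times the D4 mean, and the difference of 6535 peaks was larger than the spread between replicates of either day. The length under peaks was 66.4 ± 15.2 Mb at D2 and 6.77 ± 1.80 Mb at D4 (SD, n = 2 each), a 9.79-fold difference. Within replicate 1, taken as the earlier data set, the D2 library had 5.30 times the peaks of the D4 library, and within replicate 2 it had 6.57 times. The exact permutation test gave a two-sided p of 0.333 for both measures, the smallest that 2 libraries against 2 allow. Among peaks with a fold enrichment of at least 3 the D2 mean was 3.19 times the D4 mean, with 362 against 238 peaks in replicate 1 and 1027 against 198 in replicate 2.

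**Figure D1:**
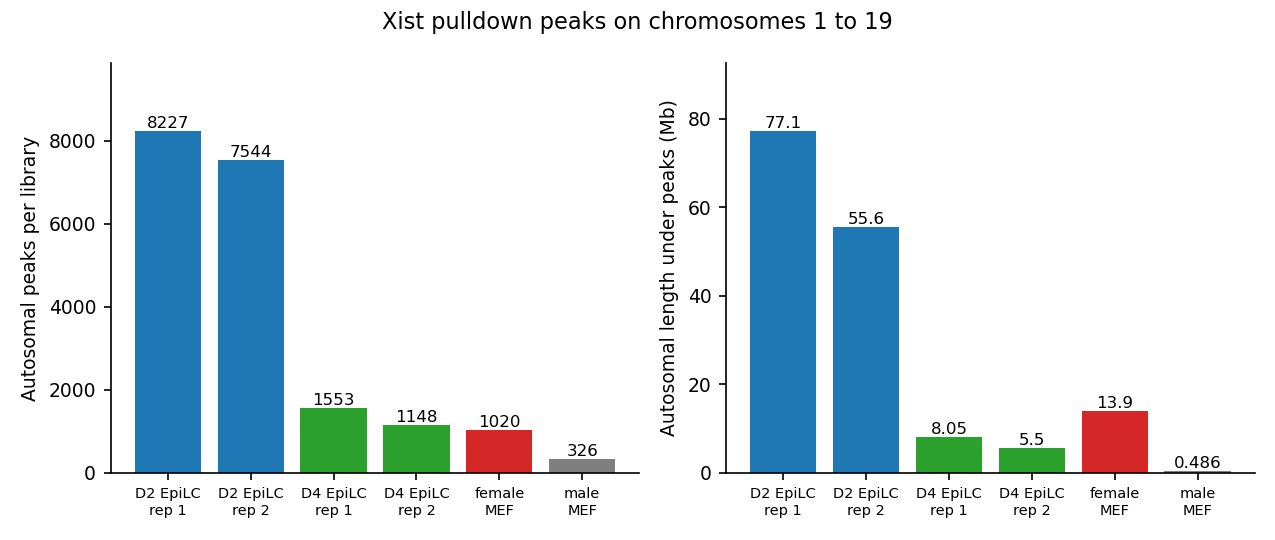
Bars show the number of autosomal peaks (left panel) and the autosomal length under peaks in Mb (right panel) for each of the 6 Xist pulldown libraries, 1 bar per library with its value on top. The D2 EpiLC libraries, with 8227 and 7544 peaks, stand above the D4 EpiLC (1553 and 1148), female MEF (1020) and male MEF (326) libraries.

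The strongest D2 regions lay close together on chromosome 6. The consensus of both D2 lists held 4885 regions over 37.5 Mb. Its first by rank of fold enrichment was at chromosome 6, 114512730 to 114515670, with fold enrichments of 14.1 and 11.8 in replicates 1 and 2. The regions at 114484153 to 114489269 (10.4 and 7.18), 114586639 to 114709389 (7.19 and 6.66) and 114450751 to 114456835 (5.61 and 4.84) of that chromosome were also among the first 5. The remaining 1 was at chromosome 5, 53975509 to 53983078, with fold enrichments of 5.54 and 6.01. The longest D2 regions were at chromosome 6, 114715646 to 115539896 (824 kb) and 113685299 to 114446152, at chromosome 16, 29708122 to 30108401, at chromosome 4, 153672939 to 154012653, and at chromosome 1, 135555928 to 135887388. All 10 of these D2 regions also overlapped a D4 peak in at least 1 D4 list.

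At D4 the same stretch of chromosome 6 led the list. The D4 consensus held 402 regions over 2.65 Mb. The segment at chromosome 6, 114515317 to 114515657 ranked first, with fold enrichments of 12.3 and 9.31 in replicates 1 and 2. It was followed by a narrow site at chromosome 2, 114583240 to 114584072 (6.26 and 5.43), and by chromosome 6 regions at 114484177 to 114489189 (9.28 and 4.38) and 114587880 to 114709351 (4.42 and 4.19). A site at chromosome 5, 145907380 to 145908925 (4.43 and 4.07) was called in both D4 lists and in female MEFs and in neither D2 list. The longest D4 regions were at chromosome 6, 113693276 to 114445576 (752 kb), 114716490 to 114875668, 114587880 to 114709351 and 114882934 to 114923051, and at chromosome 7, 151787546 to 151867365.

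Replicates of a day shared more regions than shifted lists, but most peaks of D2 replicate 1 and of both D4 lists had no counterpart. Of the D2 replicate 1 peaks, 45.3% overlapped a replicate 2 peak, against a mean of 5.04% over circular shifts, and 59.3% of replicate 2 peaks overlapped replicate 1. At D4 the shares were 22.2% (shifted mean 0.760%) and 32.6%. The base-pair Jaccard index, the shared length over the joint length, was 0.395 at D2 and 0.243 at D4, against shifted means of 0.0175 and 0.00402. Each share and index exceeded all shifts (permutation p = 0.001, the smallest they can give). For the shares this p was the same after adjustment over 30 ordered pairs of lists, and for the index it was not adjusted. Against local placements the excess was smaller, with expected shares of 21.6% and 27.4% at D2 and 10.1% and 14.5% at D4 (permutation p = 0.001, the smallest possible). The 2 days had no settled order, since the shares were 8.99 and 10.1 times their shifted means at D2 but 29.1 and 33.2 times at D4, and among peaks with a −log10 q of at least 3 the shares were 30.1% and 47.4% at D2 and 45% and 69.2% at D4.

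Many D4 regions were also called at D2. Of the 402 D4 consensus regions, 277 (68.9%) overlapped a D2 consensus region and 335 (83.3%) a region of either D2 list, against shifted means of 3.43% and 7.03% (permutation test, adjusted p = 0.00115 over 15 tests). Local placement gave 36.7% for the D2 consensus, still below the observed 68.9% (permutation p = 0.001, the smallest possible). The share was 48.7% without D4 replicate 1, 51.1% without D4 replicate 2 and 35.9% of 343 regions with lists cut to equal number. Joining all 4 EpiLC lists gave 11559 regions. Most of them, 7927, were called in 1 library only. Of the 11559, 2677 were called in both D2 libraries and in neither D4 library, 41 in both D4 libraries and in neither D2 library, and 229 in all 4. The other ways to pair the 4 libraries gave 88 and 30 regions (by replicate number) and 44 and 66 (crossed). These counts follow the length of the lists: with each list cut to its strongest peaks in equal number, 200 regions were called only at D2 and 150 only at D4. They also rested on both replicates being required, since without D2 replicate 1 the D2 count was 6662, without D2 replicate 2 it was 7369, and without D4 replicate 1 or 2 the D4 count was 364 or 418.

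More was called in female than in male MEFs, and the 2 lists shared few peaks, although more than their shifts. Female MEFs had 1020 peaks over 13.9 Mb, and male MEFs had 326 peaks over 0.486 Mb. The highest fold enrichment of the female list without male overlap was at the narrow site on chromosome 2, 114583245 to 114584059 (6.43). It was followed by chromosome 7, 67002433 to 67007635 (4.15), chromosome 14, 63422637 to 63423162 (3.77), chromosome 5, 127751652 to 127754526 (3.69) and chromosome 15, 78024953 to 78025243 (3.63). The longest such regions were at chromosome 15, 73927822 to 74191071, chromosome 2, 179331457 to 179541383, and chromosome 4, 139601940 to 139806211. The strongest male peak was at chromosome 2, 98502409 to 98507489 (fold enrichment 15.1), and the next 3 lay at the start of chromosome 9, at 3012313 to 3012815 (10.4), 3017150 to 3025540 (8.33) and 3000470 to 3007614 (6.96). As background, these stretches of the mouse genome are known for high signal in many sequencing assays. The male list also named chromosome 5, 118427283 to 118427517 (5.78), and among its 3 longest also chromosome 5, 118824528 to 118830746. Of the 1020 female MEF peaks, 17 (1.67%) overlapped a male peak, a share limited by the 326 peaks of the male list. That share was 6.78 times the shifted mean of 0.246% (permutation test, adjusted p = 0.00115). Local placement gave 0.943% (permutation p = 0.015). None of the 4 female MEF peaks with a −log10 q of at least 3 overlapped a male peak of that strength. The shifted mean was also 0%, so 4 peaks could not decide.

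Few EpiLC regions overlapped the peaks called in male MEFs. Of the D2 consensus regions, 60 of 4885 (1.23%) overlapped a male MEF peak, against a shifted mean of 0.138% (permutation test, adjusted p = 0.00115). For the D4 consensus the count was 2 of 402 (0.498%), against 0.111% (permutation test, adjusted p = 0.0769). Seen from the male list, 33.1% and 26.4% of its 326 peaks overlapped a peak of D2 replicates 1 and 2, 4.60% and 2.76% a peak of D4 replicates 1 and 2, and 5.52% a female MEF peak. Shifted means were 4.07% and 3.13% for D2, 0.502% and 0.338% for D4 and 0.759% for female MEFs (permutation test, adjusted p = 0.001 for each). Male peaks thus lay in the D2 lists more often than their shifts, although 326 peaks can reach only a small part of 4885 regions. Local placement gave 0.537% for the D2 consensus and 0.640% for the D4 consensus, so the D4 share lay below it. The male list called no peak below a fold enrichment of 2.84, while the medians of the D2 lists were 2.61 and 2.80, which limits how much of the EpiLC regions it could overlap. The D2 excess was not past the threshold when lists were cut to equal number (0.943% of 106 regions, permutation p = 0.315). The D4 share passed it for a single replicate in place of the consensus, at 0.901% without replicate 2 and 0.697% without replicate 1 (permutation p = 0.001, the smallest possible).

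A larger part of the D4 than of the D2 regions was also called in female MEFs. Of the D4 consensus regions, 121 of 402 (30.1%) overlapped a female MEF peak, against a shifted mean of 1.48%. Of the D2 consensus regions, 340 of 4885 (6.96%) did, against 1.07% (permutation test, adjusted p = 0.00115 for both). Local placement gave 17.5% for D4 and 4.84% for D2, a smaller excess (permutation p = 0.001 for both, the smallest possible). Without regions that overlap a male peak the shares were 29.3% and 6.20%. The D4 share was 19.6% without D4 replicate 2 and 21.5% without D4 replicate 1. Seen from the female MEF list the order was the other way. Of its 1020 peaks, 274 (26.9%) overlapped the D2 consensus and 82 (8.04%) the D4 consensus. Shifted means were 4.12% and 0.462% (permutation test, adjusted p = 0.00115 for both). The shares thus depend on the number of regions in each set. The difference between the D2 and D4 shares was not tested.

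**Figure D2:**
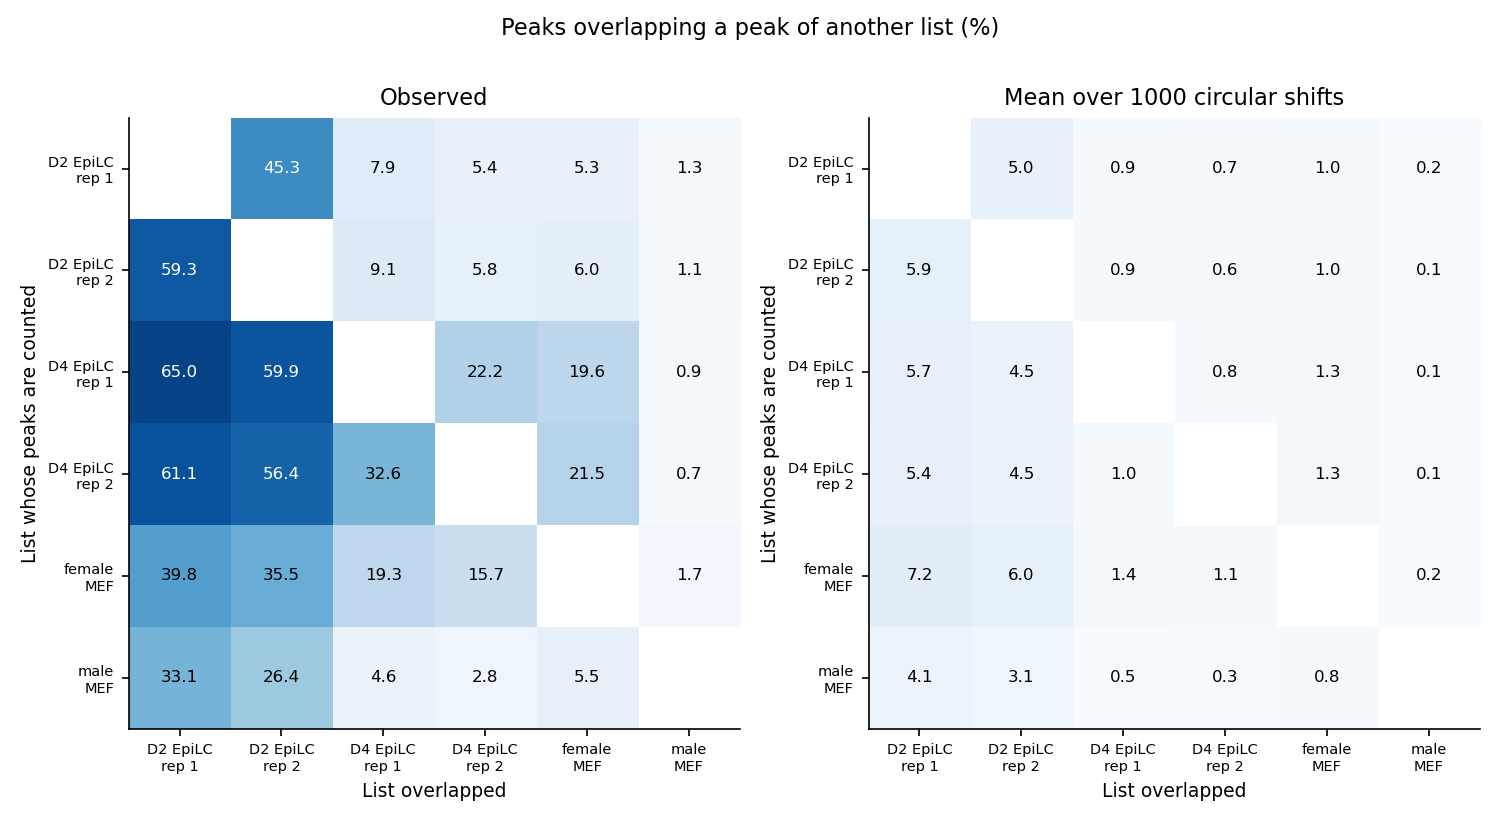
Each cell gives the percentage of peaks of the list named at the left that overlap a peak of the list named below by at least 1 bp, as observed (left panel) and as the mean over 1000 circular shifts (right panel), with darker blue for higher percentages. D4 lists overlap D2 lists for 56.4% to 65.0% of their peaks, and 0.697% to 1.67% of the peaks of the female lists overlap the male MEF list, while 2.76% to 33.1% of male MEF peaks overlap a female list.

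All 5 female lists together covered 91 segments over 1.02 Mb, where shifted lists gave a mean of 0.006 segments and at most 4 (permutation p = 0.001, the smallest possible). Each list was shifted separately, which also breaks the overlap between replicates and between D2 and D4. The test therefore cannot tell sharing with female MEFs from that overlap, and no local placement was run for it. These segments lay on 8 chromosomes. Chromosome 6 held 677 kb in 10 segments, chromosome 4 held 226 kb in 47, chromosome 15 held 79.3 kb in 12 and chromosome 5 held 28.7 kb in 14. Of the 91, 2 overlapped a male peak, at chromosome 6, 113894608 to 113894786 and chromosome 4, 153929669 to 153932198. Such a low share is not particular to these segments, since 17 of 1020 female MEF peaks and 60 of 4885 D2 consensus regions overlapped a male peak. By mean rank, the first segment without male overlap was the narrow site on chromosome 2, 114583262 to 114584051, with fold enrichments of 4.38 and 4.42 at D2, 6.26 and 5.43 at D4 and 6.43 in female MEFs. The third was on chromosome 14, 63422887 to 63423162 (3.63 to 3.82 in the 5 lists). The other 8 of the first 10 lay on chromosome 6 between 114315671 and 114439735. In each EpiLC list these 8 lay inside the same long peak and took its rank, so they are not separate regions there.

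The longest peak of every female list lay on chromosome 6 within 113684804 to 115560562, a window of 1876 kb set after the values were seen. D2 replicates 1 and 2 covered 93.6% and 92.6% of it, D4 replicates 75.3% and 71.9%, female MEFs 36.1% and male MEFs 0.0230%. The highest fold enrichment of each EpiLC list was also in the window. It made up 17.6% and 24.5% of all length called in the D4 libraries, against 2.28% and 3.13% in the D2 libraries. In its part before 114446321, a split also set after the values were seen, the female MEF list covered 677 kb and the EpiLC lists 754 to 762 kb. From there on, where the EpiLC peaks of highest fold enrichment lay, the female MEF list covered 0.965 kb and the EpiLC lists 595 to 994 kb.

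**Figure D3:**
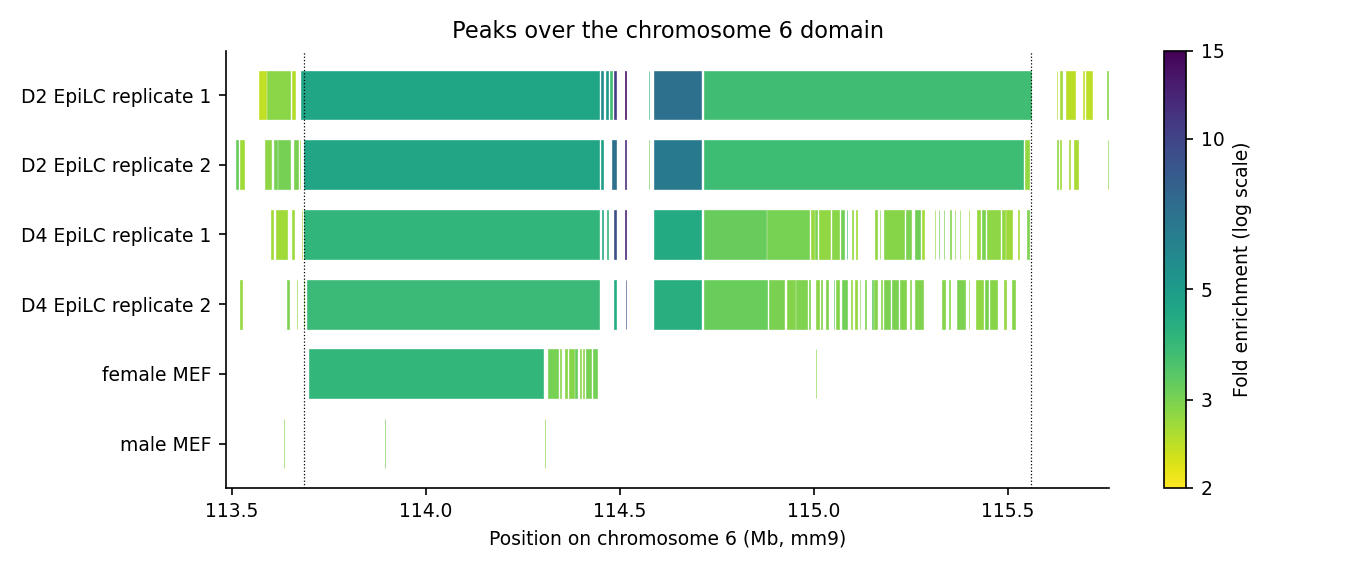
Bars mark the peaks of each of the 6 libraries (rows) along chromosome 6 in Mb on mm9, coloured by the authors' fold enrichment on a log scale, with dotted lines at the ends of the window 113684804 to 115560562. Peaks fill 71.9% to 93.6% of the window in the EpiLC lists, 36.1% in female MEFs, where they lie in its left part, and 0.0230% in male MEFs.

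Peak density differed between chromosomes in the 5 female lists. At D2, chromosomes 9 (6.58 and 6.29 peaks per Mb in replicates 1 and 2), 19 (5.67 and 4.48) and 11 (5.02 and 4.71) had the highest density, and chromosomes 3 (1.70 and 1.36), 15 (1.98 and 1.97) and 8 (2.27 and 1.97) the lowest. At D4, chromosome 4 was highest (1.73 and 1.38), followed by 9 and 6 in replicate 1 and by 6 and 15 in replicate 2. Chromosome 3 was lowest (0.116 and 0.0684), followed by 18 and 1 in replicate 1 and by 10 and 18 in replicate 2. In female MEFs, chromosomes 4 (1.46), 15 (1.10) and 7 (0.803) were highest, chromosomes 10 and 19 held 0 peaks and chromosome 3 held 6. In male MEFs, chromosomes 11 (0.226), 9 (0.206) and 15 (0.201) were highest and 3 (0.0821), 2 (0.0955) and 18 (0.0989) lowest. The spread over chromosomes passed the permutation test in the 5 female lists (adjusted p = 1.2e-05, the smallest possible) and not in the male list (adjusted p = 0.0956). Counted over bins of 1 Mb that hold a peak, an alternative chosen after seeing the data, the coefficient of variation was lower, at 0.347 and 0.363 in D4 replicates 1 and 2 in place of 0.733 and 0.788.

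**Figure D4:**
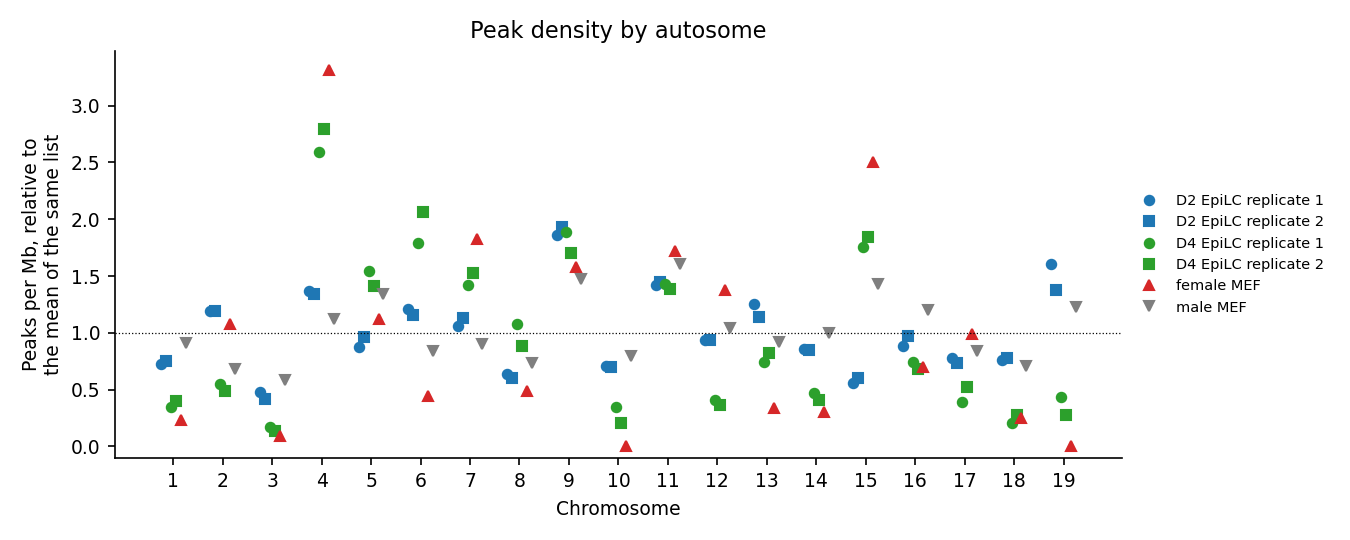
Points show the peaks per Mb of each autosome divided by the mean density of the same list (no unit), for chromosomes 1 to 19, with a colour and marker for each of the 6 libraries and a dotted line at 1. Chromosome 9 is highest in both D2 libraries (6.58 and 6.29 peaks per Mb), while chromosome 4 is highest in both D4 libraries (1.73 and 1.38) and in female MEFs (1.46).

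Densities of the 19 autosomes correlated closely between replicates, with Pearson r = 0.979 at D2 and 0.986 at D4 (Spearman 0.979 and 0.953, permutation p = 0.0001, the smallest possible). D4 densities correlated with those of female MEFs (r = 0.777 and 0.784, Spearman 0.731 and 0.771, adjusted permutation p = 0.00262 and 0.0005), while D2 densities did not pass the threshold (r = 0.265 and 0.355, Spearman 0.321 and 0.348, adjusted permutation p = 0.271 and 0.138, over 15 pairs). Between D2 and D4 lists r was 0.400 to 0.512 and Spearman 0.402 to 0.549, and only D2 replicate 2 against D4 replicate 1 passed (adjusted permutation p = 0.0448). Male MEF densities also correlated with those of D2 replicate 2, D4 replicate 1 and female MEFs (r = 0.561, 0.546 and 0.514, Spearman 0.519, 0.591 and 0.493, adjusted permutation p = 0.0399, 0.0448 and 0.0448), and those with D2 replicate 1 and D4 replicate 2 did not pass (r = 0.490 and 0.476, Spearman 0.507 and 0.491, adjusted permutation p = 0.0583 for both). These correlations are across chromosomes, not samples.

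Peaks lay in groups in the female lists. The median distance to the nearest peak was 9.05 and 10.2 kb at D2, 17.3 and 23.2 kb at D4, and 9.12 kb in female MEFs, against means of 82.4, 92.0, 375.2, 491.7 and 482.1 kb for uniform placement. In male MEFs it was 1490 kb against 2470 kb. The permutation test gave p = 0.001 in the 6 lists, the smallest possible. Bins of 1 Mb with at least 5 peaks numbered 89 and 59 at D4, where uniform placement gave 9 and 3.37, and 79 in female MEFs, where it gave 3.3. At D2 they numbered 496 and 457, fewer than the 681.7 and 571.6 of uniform placement. Male MEFs had 0 such bins.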

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

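Of 162 alternative values for 26 results, 135 kept their direction and side of the threshold or moved little. For the 10 overlap results, 83 of 92 alternatives lay above their placements with a permutation p under 0.05. Of these 83, 4 belonged to the overlap of D4 with male MEFs, which did not pass in its main form (permutation p = 0.0769), and so changed side. Alternatives without the chromosome 6 window, counting bins of 1 Mb in place of peaks, and leaving out a replicate for regions called only at D2 or D4 were chosen after seeing the data. With −log10 q of at least 3, the D2 minus D4 difference was 107.5 peaks and 2.05 Mb. With fold enrichment of at least 3 it was 476.5 peaks and 5.73 Mb, and with peaks joined within 10 kb 4098 peaks. D2 exceeded D4 under each of these. With the replicate number as a block, the mean difference was 6535 peaks and 59.6 Mb, equal to the unpaired value by construction. The counts of 2677 and 41 regions called at a single day cannot change under the block either, and it was run for no other result. These counts were 1729 for D2 with joined peaks, 1088 and 21 with the upper 50% by fold enrichment, and 200 and 150 with equal numbers per list, lower for D2 and higher for D4. Leaving out a replicate gave 2812 to 7369 regions for D2 and 56 to 418 for D4.

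Overlap with the male list was the least settled. With −log10 q of at least 3 it was 0% for female MEFs (4 peaks), D2 (46 regions) and D4 (9 regions), with a p of 1 in the permutation test. Their shifted means were 0%, 0.0152% and 0.0111%, so these few regions could not decide. With equal numbers per list D2 was at 0.943% and no longer passed. For D4 it was 1.99% with peaks widened by 5 kb, 0.870% with the union and 0.697% to 0.901% without a replicate, all past the threshold, but 0.498% against 0.640% placed with a local shift, below its placements. The cause was not tested. The spread of density, as a coefficient of variation, rose from 0.733 and 0.788 to 1.15 and 1.33 in D4 replicates 1 and 2 when covered length replaced peak number. With bins of 1 Mb in place of peaks it was 0.347 and 0.363 at D4, 0.224 and 0.216 at D2 (0.367 and 0.363 by peaks) and 0.656 in female MEFs (0.941), still past the threshold. The male nearest distance with the upper 50% was 4429 kb and no longer passed. No replicate could be left out of the replicate overlaps. The planned counts of genes under regions were not run, since no mm9 annotation was used here. Depth is unknown and limits every count of peaks.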

Other observations

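Beyond the chromosome 6 window, other stretches were covered in all 5 female lists. At the far end of chromosome 4, the bin from 153 to 154 Mb was covered to 79.0% and 73.7% at D2, 41.8% and 31.7% at D4 and 48.9% in female MEFs, against 0.321% in male MEFs. Chromosome 4 from 150 to 151 Mb was covered to 37.8% and 31.5% at D2, 18.8% and 11.9% at D4 and 22.7% in female MEFs, against 0 in male MEFs. Chromosome 4 from 139 to 140 Mb was covered to 42.3% and 27.4% at D2, 13.1% and 6.54% at D4 and 59.4% in female MEFs, against 0.0179% in male MEFs. Chromosome 15 from 101 to 102 Mb was covered to 65.6% and 58.6% at D2, 26.3% and 12.6% at D4 and 24.8% in female MEFs, against 0.137% in male MEFs. Chromosome 5 from 113 to 114 Mb was covered to 54.1% and 40.4% at D2 and 40.4% in female MEFs but to 8.61% and 9.17% at D4. These bins were ranked after seeing the data by the lowest share covered among the 5 female lists. Over all autosomes the lists covered 3.32% and 2.39% at D2, 0.347% and 0.237% at D4, 0.598% in female MEFs and 0.0209% in male MEFs. The male shares of 0.321% and 0.137% were thus above the male mean, and those of 0 and 0.0179% below it. Low male values in these bins partly reflect how little the male list covered. The narrow site on chromosome 2 ranked 12 and 11 by fold enrichment at D2, 3 and 2 at D4 and 1 in female MEFs, and was not called in male MEFs.

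All tests of explanations given here were chosen after the results were seen. The long chromosome 6 domain was called in the 5 female lists. In the window the male MEF list covered 0.0637% of the length that the female MEF list covered. Its share of the window (0.0230%) was near its share of the autosomes (0.0209%), against 36.1% and 0.598% for the female MEF list. The male list called peaks down to a fold enrichment of 2.84, and the longest female MEF peak had 4.00, in libraries of unknown depth. The comparison bears on the part before 114446321, since the female MEF list covered 0.965 kb from there on. With 1 male library, background that does not depend on Xist cannot be told apart from other causes. A rearrangement carried only by the EpiLC cells, which might bring this stretch close to the X chromosome, would leave it uncalled in female MEFs, yet their list covered 89.1% of the mean EpiLC length before 114446321 and 0.120% from there on. Neither part settles this explanation, since window and split were set after the lists were seen and rest on 1 female MEF library, and a difference between cell types stays open and untested. A rearrangement shared by all female cells used, or an effect of the input, was not tested.

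More peaks were called at D2 than at D4. The lowest ratio within a replicate number was 5.30. This argues against a difference between an earlier and a later data set only if both libraries of a replicate number belong together. The labels do not state this for replicate 2. Lower coverage at D4 cannot be told apart from a difference of stage, which the design names and which stays open. The median −log10 p among peaks of similar fold enrichment was lower at D4 (3.21 and 3.09) than at D2 (3.74 and 3.32) in both replicates, which goes with lower coverage. The same median was 3.05 in female MEFs and 5.14 in male MEFs, the list with the fewest peaks. It therefore did not follow peak number over the 6 lists. Among peaks with fold enrichment of at least 3, the lowest ratio was 1.52 (replicate 1, exact 95% interval 1.29 to 1.80, counting error only), while replicate 2 gave 5.19 (4.45 to 6.07).

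The distal ends of chromosomes, taken as the last 5 Mb, held 10.6% and 10.9% of D2 peaks, 23.6% and 24.6% of D4 peaks, 21.7% of female MEF peaks and 11.3% of male MEF peaks, against shifted means between 3.82% and 4.15% (permutation p = 0.001 in the 6 lists, the smallest possible). Background that does not depend on Xist is consistent with the share of 1-Mb bins, since 10.5% of the bins that hold a male peak were distal, against 8.31% to 12.6% in the female lists. For the higher share of peaks in the D4 and female MEF lists this background cannot be told apart from stage and cell type, which were not tested. With each chromosome left out in turn, the lowest shares came without chromosome 4, at 17.5% and 17.2% in D4 replicates 1 and 2 and 15.9% in female MEFs. These lay above the exact 95% interval of the 1 male library (8.12% to 15.3%), but only D4 replicate 1 lay above the highest share of its own shifted lists (16.1%, against 17.7% and 17.4% for the others), and the distal share of bins at D4 (9.76% and 10.0%) was not above the male one.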
